A study of Mus musculus with 9 samples.

How the data were processed

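The series holds RNA-seq of 9 mouse libraries labelled as BMSCs from bone at 8 weeks, with 3 replicates each of a control, GEL and Gel@MDI. Per the labels' protocols, total RNA was extracted with a column kit, mRNA was purified, and TruSeq libraries were sequenced as paired ends on a NovaSeq instrument. The submitters' processing notes name bcl2fastq, FastQC, Trimmomatic, HISAT2, HTSeq and DESeq2 with no versions or roles, and the build mm10. Strand settings and filters are not given in the sources used here, so overlapping and antisense genes cannot be told apart.

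The deposited table gives raw counts per gene for each library, as its whole numbers and differing totals show, and FPKM values by the authors beside them. It lists 56691 genes, of which 2639 have no symbol. Recomputed FPKM, the count divided by the exonic gene size of the table and by the library's own total, equalled all values of the 8 deposited FPKM columns with a replicate number within 0.0051. A further 1 per-sample column, an FPKM column without a replicate number, was not used, and the FPKM of all 9 libraries given here are the recomputed ones. FPKM are therefore relative to the counts assigned to genes. Library totals were 14926675 to 19623109 counts, so a gene at 1 FPKM rests on few counts where its exonic size is small. For the genes matched to the GRCm38 annotation (52036), only 1448 (2.78%) had the same start in the table, so coordinates are given as the table states them, with no build attached. No libraries of one group agreed within sampling noise (the lowest chi-square per degree of freedom was 19.0, over genes with at least 10 counts in the pair), so all 9 were counted.

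The design had assumed FPKM values tested with limma. Because the table also held raw counts, the test became edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest, two-sided, TMM scaling, edgeR 4.0.16 in R 4.3.3), the choice stated for that case before the data were examined. Limma on log2 of FPKM became an alternative. All 9 libraries entered a single fit with a shared estimate of spread. Genes with FPKM of at least 1 in at least 3 libraries were kept (15148), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Comparisons were Gel@MDI against control, GEL against control and Gel@MDI against GEL. A log2 fold change is the group listed first over the other. The SE of a gene's log2 fold change was derived from edgeR's test, as the absolute log2 fold change divided by the square root of F.

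A set of 41 gene lists (639 distinct genes, of which 2 were not in the table) was fixed before the data were examined. They cover mitochondrial and metabolic genes, bone, cartilage and fat genes, inflammation, stress, growth and cell type markers. Each list was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 41 lists within a comparison. Alternatives were camera with an estimated correlation, and fry, whose directional test asks whether members move one way on balance and whose mixed test asks whether they change in either direction. With the estimated correlation no list passed in any comparison. The count of members past the per-gene test was 0 in every list, and the count adjusted over the list alone is given where it was not 0. Where a symbol stood on more than 1 row, the row with the higher total count was used.

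Named genes followed a rule fixed beforehand. Per comparison it took up to 10 genes per direction with the largest change among those past the test, with a mean FPKM of at least 5 in the higher group, groups that do not overlap and a symbol that is not provisional. Since no gene passed, 5 per direction with the smallest p that met the other criteria are named and said not to pass. In each list up to 4 members with the smallest p could be named, and Rhot1 is given in every library. Other genes are named as chosen after their values were seen, among them the markers that describe single libraries.

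The scripts were tested on simulated data built from the means and library sizes of these libraries, with 200 of 15148 genes changed between Gel@MDI and control. There edgeR recovered 5 of 100 genes changed by 2 times and 53 of 100 changed by 4 times, with 1 false call. DESeq2 1.42.0 recovered 42 and 85 with 58 false calls, and limma 4 and 60 with 5. Most simulated changes of 2 times were thus missed by edgeR at this spread. This was a single simulated data set, with each gene drawn independently from the spread that edgeR had estimated. It held no library-wide shifts, so the counts of false calls may not carry over to these libraries.

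Alternatives set beforehand were DESeq2, other filters, pseudocounts of 1, 0.1 and 0.01 with limma, median ratio, quantile and TPM scaling, library weights, robust dispersion, only the 2 groups compared, a replicate block, a minimum fold of 2, and each library left out in turn. Total count scaling, neutrophil and cortical neuron list means as covariates, the 2 libraries with most neutrophil transcript left out, and the 3 libraries numbered 1 left out were chosen after the data were seen. Differences in list means between groups were tested with two-sided exact permutation tests, which cannot go below 0.1 with 3 against 3. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.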

Results

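RNA was sequenced from 9 mouse libraries labelled as BMSCs with bone as their tissue, in 3 groups of 3. The groups were a control, GEL (taken to be the plain hydrogel) and Gel@MDI (the hydrogel with dimethyl itaconate, an anti-inflammatory ester, and nanoparticles that carry Miro1, a mitochondrial transport GTPase). All 9 carried the label 8 weeks, which the labels used here do not tie to an age or to a time after treatment. Library totals lay between 14926675 counts (GEL replicate 3) and 19623109 counts (control replicate 2). Nothing in the labels says whether the replicates came from separate animals, so the per-gene p-values measure the spread between these libraries, which may be technical. Camera's p-values at the preset correlation of 0.01 treat list members as almost independent, so they rest mainly on the spread between genes. In the lists it called between Gel@MDI and control, the estimated correlation ran from 0.28 (osteocyte) to 0.98 (neutrophil), with 0.9 for the cell cycle.

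Transcripts of several cell types were present, and their amounts differed between libraries of the same group. The neutrophil list took 8.73% of the counts in control replicate 1 and 7.29% in GEL replicate 1. In the other libraries it took between 1.20% (Gel@MDI replicate 1) and 4.53% (control replicate 3). S100a9, a neutrophil calcium-binding protein, was the most abundant gene in control replicate 1 and GEL replicate 1, while a type I collagen gene (Col1a1 or Col1a2) led the others. The first principal component held 58.8% of the variance and ran from control replicate 1 (-86) and GEL replicate 1 (-75.8) to Gel@MDI replicate 1 (80.4). Skeletal muscle genes took 1.29% of the counts in control replicate 2 and 0.0384% in control replicate 3. Neuronal genes were uneven too, with Snap25, a synaptic vesicle fusion protein, between 1.26 and 42.0 FPKM and highest in Gel@MDI replicate 3. Over all tested genes the biological coefficient of variation was 0.332, and a gene had a median of 28.6% of its variance between groups. With no effect the mean share would be 25% and the median share lower, so the 2 values are not directly comparable.

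Rhot1, which encodes Miro1, was present at similar levels in all 9 libraries. Its levels were 4.98, 6.59 and 6.61 FPKM in the control, 5.56, 6.71 and 7.05 in GEL, and 7.70, 7.72 and 6.91 in Gel@MDI. The means were 6.06 ± 0.937, 6.44 ± 0.778 and 7.44 ± 0.463 FPKM (SD, n = 3 libraries each). The log2 fold change of Rhot1 was 0.24 (SE 0.12) between Gel@MDI and control, 0.07 between GEL and control and 0.17 between Gel@MDI and GEL, and none passed edgeR's test (adjusted p = 0.357, 0.99 and 0.874). The gene (ENSMUSG00000017686) is listed on chromosome 11 from 80099845 to 80158733 on the plus strand. Positions are those of the deposited table, whose gene starts equal those of the GRCm38 annotation for only 2.78% of genes, so no build is attached to them. Acod1, whose enzyme makes itaconate and which was chosen after its values were seen, ranged from 1.06 to 12.2 FPKM, with both ends in Gel@MDI.

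**Figure D1:**
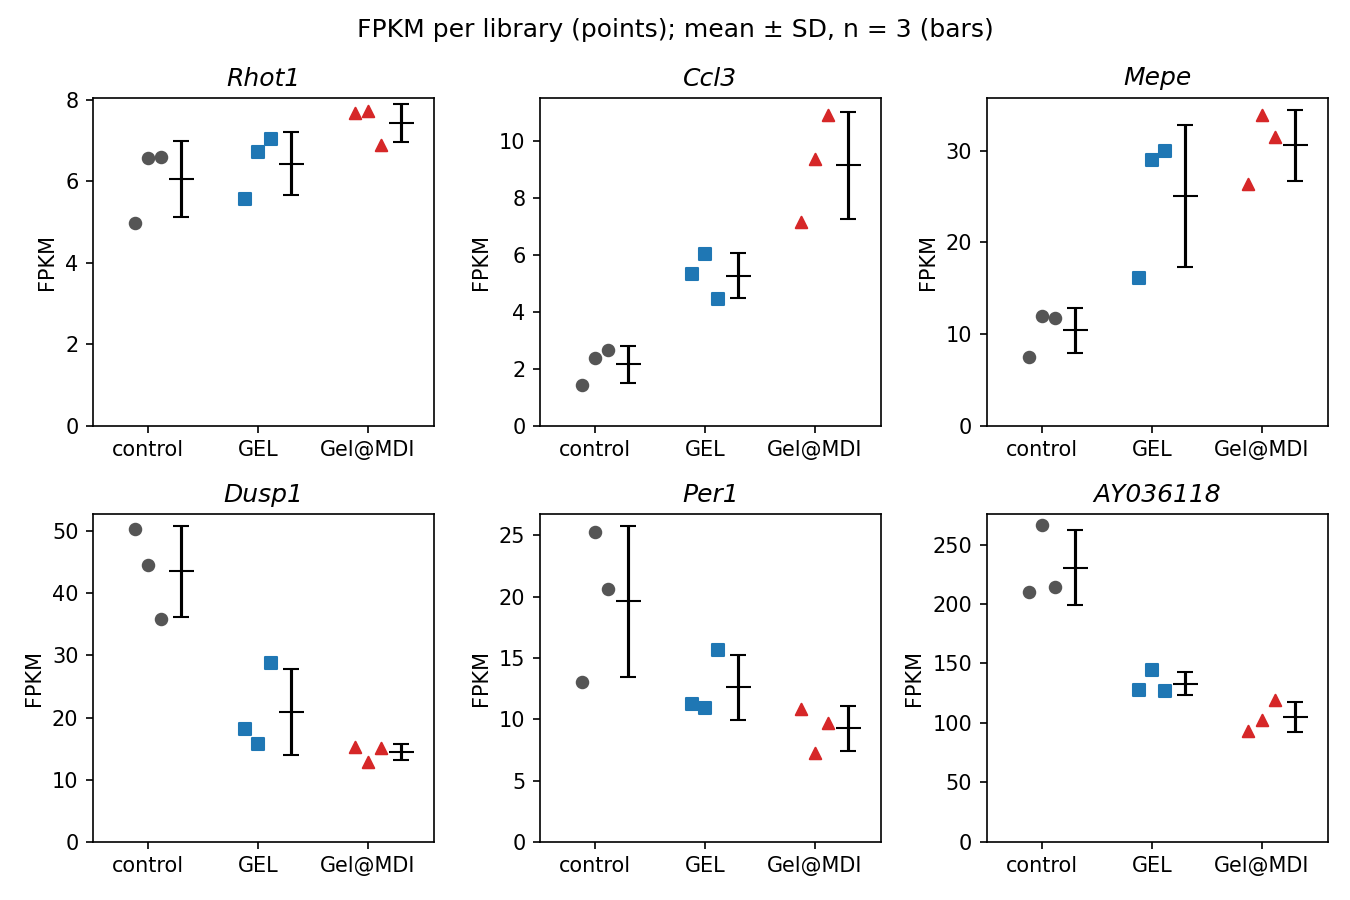
FPKM of 6 genes in each of the 9 libraries (points) by group, with the mean and SD of the 3 libraries (bars), on linear axes from 0. Ccl3 and Mepe are higher and Dusp1 and AY036118 lower in every GEL and Gel@MDI library than in every control library, while the Rhot1 means are 6.06, 6.44 and 7.44. The rule that named Ccl3, Mepe, Dusp1 and AY036118 required groups that do not overlap, so their separation from control was fixed by the selection.

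Gel@MDI against control addresses what the loaded hydrogel changes in the bone transcriptome. Bone-forming and bone-resorbing genes were higher in Gel@MDI as sets, and neutrophil, cell cycle and nuclear-encoded respiratory chain genes were lower as sets. Exact permutation tests of the list means gave p = 0.1, the smallest possible, for the osteoblast, osteoclast, neutrophil, cell cycle and complex IV lists. They gave 0.3 for complex I and 0.4 for complexes II and III and for complex V. The osteoblast list was higher, with 19 of its 20 measured members above 0 and a median log2 fold change of 0.83 (camera, adjusted p = 5.01e-06, but adjusted p = 0.758 with an estimated correlation). Mepe, a phosphoglycoprotein of mineralizing bone, was at 30.6 ± 3.83 FPKM in Gel@MDI and 10.4 ± 2.50 in control, a log2 fold change of 1.5 (SE 0.23). It was the 1 gene of this list past the threshold adjusted over the list alone (adjusted p = 0.00326). Dlx5, a homeobox factor of osteoblasts, had a log2 fold change of 1.42 (SE 0.50), and Bmp4, a bone morphogenetic protein, of 1.26 (SE 0.42), and neither passed. The osteoclast list was higher as well, with 10 of 11 members above 0 and a median of 0.88 (camera, adjusted p = 6.62e-05, but adjusted p = 0.758 with an estimated correlation). Here 6 genes passed when adjusted over the list alone, among them Dcstamp, which mediates osteoclast fusion (log2 fold change 1.44, SE 0.29), Oscar (1.02, SE 0.29), Atp6v0d2 (1.52, SE 0.45) and Ctsk, the collagen-degrading cathepsin K (1.07, SE 0.32). Without control replicate 1, the library richest in neutrophil transcripts, the osteoblast and osteoclast medians were 0.36 and 0.58, still past the camera test. With the neutrophil list mean as a covariate they were 0.19 and 0.7 (camera at the preset correlation, adjusted p = 0.0035 and 6.46e-10). An estimated correlation was not applied to that fit. Over the libraries, the difference in the osteoclast list mean was 0.77 (SE 0.25) without the covariate and 0.64 (SE 0.33) with it.

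The matrix and signalling lists had the same direction. All 23 measured extracellular matrix genes were above 0, with a median log2 fold change of 1.03 (camera, adjusted p = 3.7e-07), and the elastin gene Eln had 1.57 (SE 0.66) and the cross-linking enzyme gene Lox 1.32 (SE 0.46). WNT and BMP signalling genes had a median of 0.58 with 19 of 20 above 0 (adjusted p = 6.62e-05), with Nog, a BMP antagonist, at 1.06 (SE 0.38) and Smad7, an inhibitory SMAD, at 0.45 (SE 0.13). Osteocyte genes had a median of 1.01 with 6 of 7 above 0 (adjusted p = 0.0134), and Sost, the osteocyte WNT inhibitor, was the 1 gene past the threshold adjusted over the list alone (log2 fold change 1.71, SE 0.45). Chondrogenic (6 of 6 above 0, median 1.02, adjusted p = 0.0128), angiogenic (11 of 12, median 0.57, adjusted p = 0.00663) and stromal cell genes (14 of 15, median 0.35, adjusted p = 0.0213) were higher as sets too. So were neural and Schwann cell genes (8 of 8, median 1.27, adjusted p = 0.0128), led by the neuronal genes Tubb3 (log2 fold change 2.23, SE 0.75) and Map2 (2.08, SE 0.86). Each of these 7 lists had adjusted p = 0.758 with an estimated correlation. The chondrogenic and stromal calls ended without control replicate 1 (camera, adjusted p = 0.0544 and 0.47), the osteocyte call without control replicate 2 (0.0542) or Gel@MDI replicate 2 (0.0573), and the stromal call also without Gel@MDI replicate 2 (0.0857). Calls that were kept had smaller medians without control replicate 1 (extracellular matrix 0.56, osteocyte 0.61, angiogenic 0.26) or without Gel@MDI replicate 1 (neural 0.54). Neutrophil transcripts were lower in the same libraries, and with the neutrophil list mean as a covariate the calls of these 7 lists ended. The medians were then 0 for the extracellular matrix (adjusted p = 0.79), 0.04 for WNT and BMP (0.235), 0.1 for osteocyte (0.178), -0.04 for chondrogenic (0.685), -0.05 for angiogenic (0.968), -0.08 for stromal (0.543) and 0.08 for neural genes (0.464).

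Among the lists that were lower, all 26 cell cycle genes were below 0 with a median log2 fold change of -0.57 (camera, adjusted p = 1.74e-09), and Ccne2, a cyclin of S-phase entry, had -0.56 (SE 0.20). All 11 neutrophil genes were below 0 with a median of -1.28 (adjusted p = 4.98e-06). Cxcr2, a chemokine receptor of neutrophils, had -1.60 (SE 0.65), and the granule collagenase gene Mmp8 had -1.30 (SE 0.55). Nuclear-encoded respiratory chain genes had smaller shifts, whose sign depended on the scaling: with TPM, which put the median of all genes at 0.263, the medians of complexes I, II and III, IV and V were 0.03, 0.04, 0 and 0.05, and only the complex I call was kept (adjusted p = 0.00494, 0.22, 0.0897 and 0.266). Complex I genes had a median of -0.25 with 35 of 36 below 0 (adjusted p = 1.41e-05), complexes II and III -0.24 with 13 of 14 (adjusted p = 0.0089), complex IV -0.29 with 11 of 11 (adjusted p = 0.00663) and complex V -0.22 with 14 of 14 (adjusted p = 0.00911). Ndufa3 and Ndufa1, subunits of complex I, had log2 fold changes of -0.47 (SE 0.14) and -0.56 (SE 0.18). Mitochondrial ribosome (median -0.24, 23 of 24 below 0, adjusted p = 0.00257), cytosolic ribosome (-0.28, 26 of 27, adjusted p = 9.07e-05), glycolysis (-0.51, 15 of 18, adjusted p = 0.00385) and fatty acid oxidation genes (-0.19, 14 of 15, adjusted p = 0.0128) were lower as well. Slc16a3, a lactate exporter, had -1.59 (SE 0.51), and Slc25a20, the carnitine carrier, -0.51 (SE 0.19). With TPM the medians were 0.03 for the mitochondrial ribosome, 0 for the cytosolic ribosome, 0.09 for fatty acid oxidation and 0.07 for interferon-stimulated genes, and the calls of the mitochondrial ribosome and fatty acid oxidation ended (adjusted p = 0.162, 0.00494, 0.118 and 0.0121). Interferon-stimulated genes had a median of -0.32 with 17 of 20 below 0 (adjusted p = 0.0153), but a median of 0.14 (adjusted p = 0.832) without control replicate 3. With an estimated correlation the interferon list had adjusted p = 0.834 and the other 10 lists that were lower adjusted p = 0.758. Without control replicate 1 the calls of complex IV, glycolysis and the mitochondrial ribosome ended (adjusted p = 0.0764, 0.0746 and 0.0746). Those of complexes II and III, complex V and fatty acid oxidation ended without control replicate 2 (0.169, 0.118 and 0.123), and fatty acid oxidation also without Gel@MDI replicate 3 (0.069). Kept calls had smaller medians for neutrophil (-0.85) and cytosolic ribosome genes (-0.15) without control replicate 1 and for cell cycle genes (-0.36) without Gel@MDI replicate 1, and larger ones for complexes I, II and III, V and fatty acid oxidation without control replicate 3 (-0.38, -0.39, -0.34 and -0.34). With the neutrophil covariate the calls of the cell cycle (median -0.05, adjusted p = 0.178), glycolysis (-0.04, 0.669), the cytosolic ribosome (-0.02, 0.594), the mitochondrial ribosome (-0.02, 0.543) and complex IV (-0.08, 0.225) ended.

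The inflammatory lists gave a mixed picture. In the M1 and NF-kB list, 12 of 18 measured genes were above 0 and the median was 0.27 (camera, adjusted p = 0.182), while fry's mixed test, which asks whether members change in either direction, gave an adjusted p of 0.0218. When adjusted over the list alone 4 genes passed. The chemokine genes Ccl3 and Ccl4 had log2 fold changes of 2.03 (SE 0.28) and 1.52 (SE 0.42), Ptgs2, the inducible cyclooxygenase, had 1.36 (SE 0.37), and Nfkbia, the NF-kB inhibitor, had -1.01 (SE 0.27). Ccl3 was at 9.16 ± 1.89 FPKM in Gel@MDI and 2.16 ± 0.654 in control (SD, n = 3), from 99 to 138 and from 18 to 36 counts per library. The M2 list was not past the test (median 0.21, 8 of 12 above 0, adjusted p = 0.767), with the mannose receptor gene Mrc1 at 0.97 (SE 0.40) and Il4ra at -1.36 (SE 0.57). Macrophage and monocyte markers had a median of -0.14 with 8 of 17 above 0 (adjusted p = 0.767).

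The mitochondrial lists the design points to were not past the camera test between Gel@MDI and control. Mitochondrially encoded respiratory chain genes had a median log2 fold change of 0.20 (9 of 13 above 0, adjusted p = 0.727), although 6 of these 13, such as mt-Co2 (545 to 1085 counts beside 158597 to 325933 for mt-Co1), had few counts and near-identical nuclear copies and are uncertain. Mitochondrial transport, dynamics and transfer genes had 0.04 (adjusted p = 0.795), biogenesis and mitophagy genes 0.11 (0.874), TCA cycle genes -0.11 (0.225), antioxidant enzymes 0.04 (0.842) and NRF2 targets 0.15 (0.727). Of the remaining lists, the adipogenic had a median of 0.59 (adjusted p = 0.405), the senescence and p53 0.33 (0.325), the immediate early and heat shock 0.28 (0.487), the hypoxia 0.09 (0.798) and the integrated stress response -0.11 (0.727). In the adipogenic list, Cebpb, a C/EBP factor also used by myeloid cells, passed when adjusted over the list alone (log2 fold change -1.77, SE 0.45). Among cell type lists not past the test, the skeletal muscle median was -0.65 (adjusted p = 0.668), erythroid 0.21 (0.568), endothelial 0.20 (0.325), megakaryocyte and mast cell -0.19 (0.811), pericyte and smooth muscle 0.05 (0.874), B and plasma cell 0.03 (0.727) and T and NK cell -0.02 (0.746). The mean had the opposite sign to the median in the NRF2, integrated stress response, macrophage, megakaryocyte, pericyte and B cell lists, and camera's direction differed from the median in the NRF2, macrophage and B cell lists.

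No single gene passed edgeR's quasi-likelihood test between Gel@MDI and control, where 0 of 15148 genes had a Benjamini-Hochberg adjusted p below 0.05 and the smallest was 0.203. At an unadjusted p below 0.05 there were 1834 genes (1179 higher, 655 lower), where 757 would be expected by chance, and DESeq2 called 39 (12 higher, 27 lower). The 3 libraries of one group all lay above those of the other for 4342 genes (28.7%, where chance gives 10%). Besides Ccl3, Mepe and Dcstamp, the genes with the smallest p among those higher in Gel@MDI were Snai1, a repressor of epithelial genes (log2 fold change 1.06, SE 0.23), and Gabra3, a GABA receptor subunit (1.85, SE 0.42). On the lower side these were AY036118 (-1.20, SE 0.13), Dusp1, a phosphatase of MAP kinases (-1.67, SE 0.27), Ighv5-17, an immunoglobulin variable segment (-2.82, SE 0.54), Per1, a circadian repressor (-1.13, SE 0.25), and Rbm15, an RNA-binding protein gene (-0.53, SE 0.12). Variable segments such as Ighv5-17 belong to a family of near-identical copies, so their counts are uncertain. Levels of AY036118 were 105 ± 12.9 FPKM in Gel@MDI and 230.5 ± 31.5 in control, and those of Dusp1 were 14.5 ± 1.34 and 43.5 ± 7.28 (SD, n = 3). Ccl3 is listed on chromosome 11 from 83538670 to 83540181, Mepe on chromosome 5 from 104473195 to 104486477, Dusp1 on chromosome 17 from 26724564 to 26781102 and AY036118 on chromosome 17 from 40158994 to 40159718. Neutrophil genes took 2.19 ± 0.914% of the counts in Gel@MDI and 5.45 ± 2.93% in control, and their mean log2 CPM differed by -1.29 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). With the mean of the neutrophil list as a covariate, a choice made after the data were seen, 7 of the 19 calls of other lists kept their direction and their side of the threshold. Among those 7 the medians went from 0.83 to 0.19 (osteoblast), -0.25 to -0.14 (complex I), -0.24 to -0.14 (complexes II and III), -0.22 to -0.12 (complex V), -0.19 to -0.13 (fatty acid oxidation), 0.88 to 0.7 (osteoclast) and -0.32 to -0.71 (interferon).

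**Figure D2:**
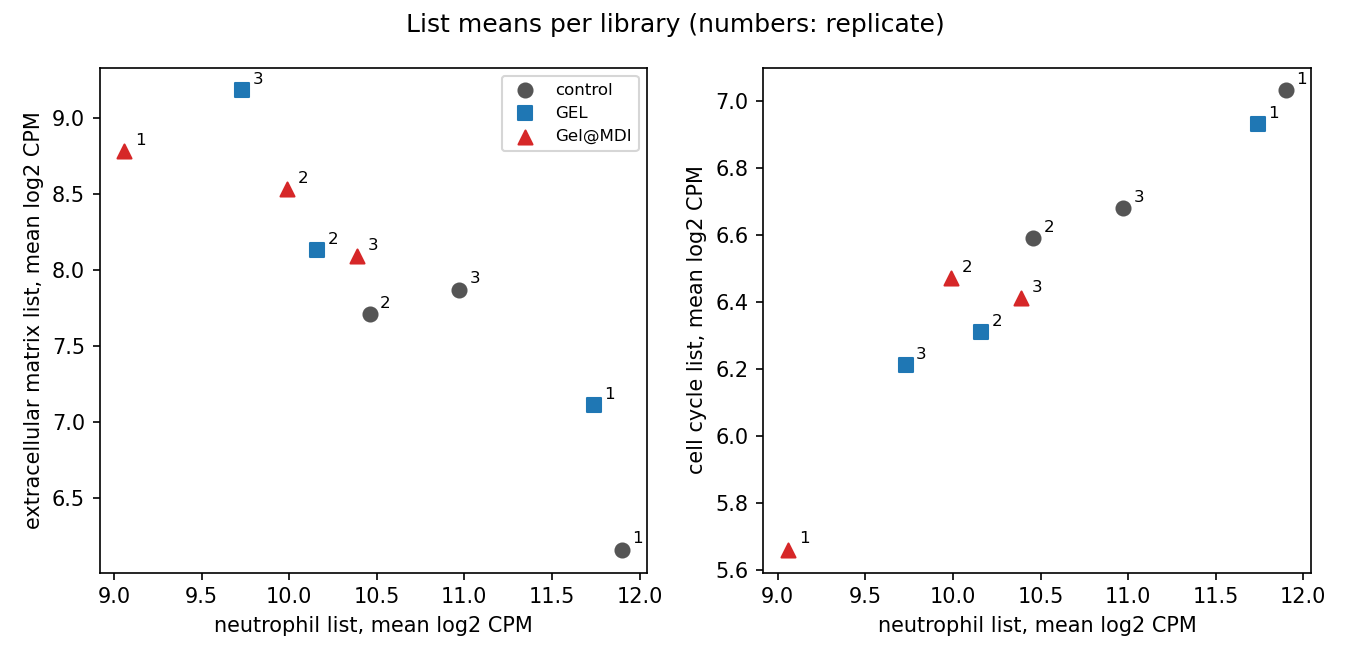
Mean log2 CPM of the extracellular matrix and cell cycle lists (panels) against that of the neutrophil list in the 9 libraries (points, numbered by replicate and coloured by group). Over the 9 libraries r was -0.91 for the extracellular matrix list and 0.96 for the cell cycle list (-0.79 and 0.94 without control replicate 1 and GEL replicate 1), 2 of 7 lists compared with the neutrophil list. The others were WNT and BMP (-0.97, and -0.95 without those libraries), cytosolic ribosome (0.86 and 0.58), osteoblast (-0.79 and -0.17), complex I (0.61 and 0.05) and osteoclast (-0.55 and -0.29). Complex I and osteoclast were not past the permutation test of Pearson's r over the 9 libraries (adjusted p = 0.0967 and 0.123), and with Spearman's rank correlation the cytosolic ribosome was not either (permutation, adjusted p = 0.0722).

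**Figure D3:**
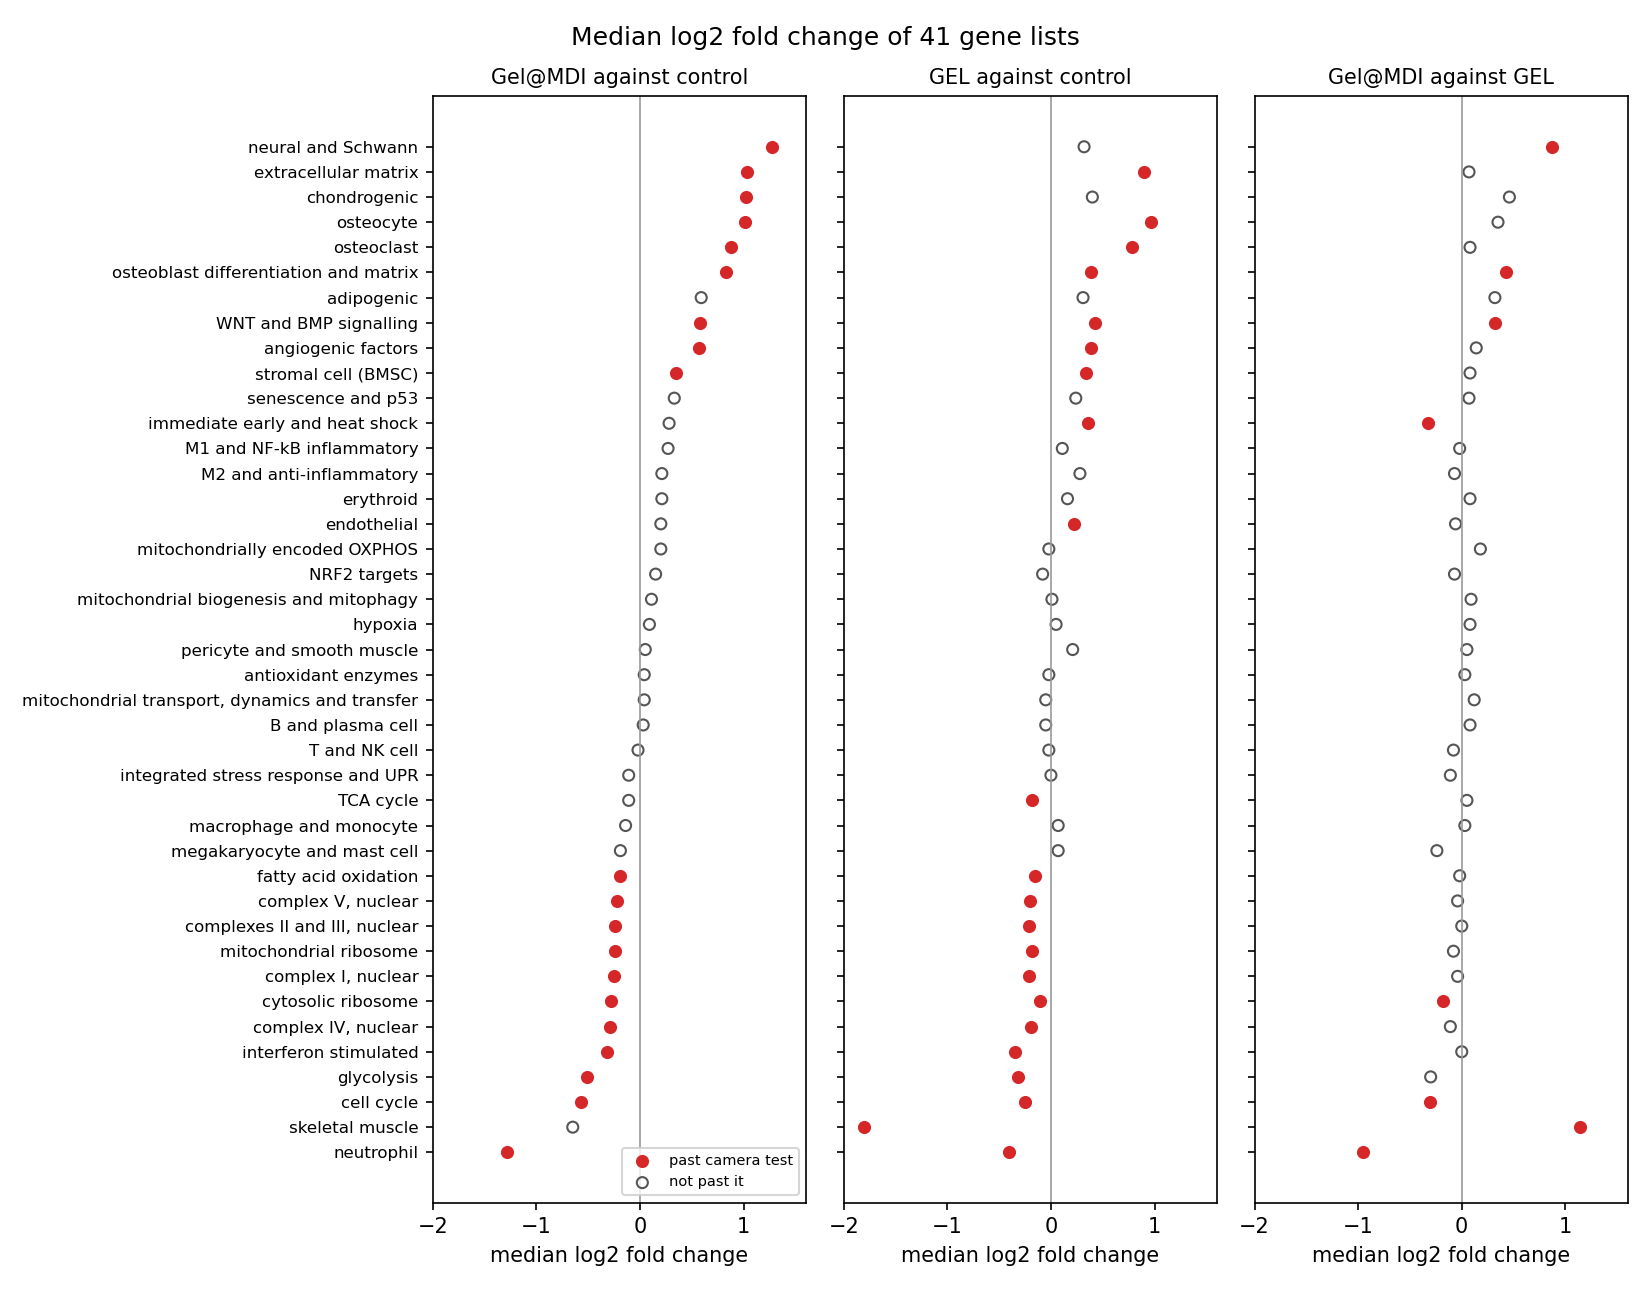
Median log2 fold change of each of the 41 fixed gene lists (rows) in the 3 comparisons (panels), with filled points for lists past the camera test at an adjusted p below 0.05 and open points for the rest. Filled points number 20, 22 and 8 from left to right, and none of them passes with an estimated correlation.

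GEL against control addresses what the plain hydrogel changes. Matrix, osteoclast and osteoblast genes were higher as sets in GEL, and respiratory chain, muscle and interferon genes lower. Exact permutation tests of the list means over the libraries gave p = 0.1 (the smallest possible) for osteoclast, 0.4 for extracellular matrix and 0.5 for osteoblast genes. They gave 0.3 for complex I, 0.7 for skeletal muscle and 0.9 for interferon genes. Apart from osteoclast genes, these set calls thus rest on camera. All 23 extracellular matrix genes were above 0 with a median log2 fold change of 0.90 (camera, adjusted p = 9.94e-13), and Mmp13, the collagenase of bone remodelling, had 0.83 (SE 0.33). The osteoclast list had a median of 0.78 with 10 of 11 above 0 (adjusted p = 9.94e-13). Dcstamp had 1.22 (SE 0.29), Ctsk 1.03 (SE 0.32) and Acp5, tartrate-resistant acid phosphatase, 0.80 (SE 0.30), and 1 gene of this list, Dcstamp, passed when adjusted over the list alone. The osteoblast list had a median of 0.39 with 15 of 20 above 0 (adjusted p = 2.17e-05), with Mepe at 1.24 (SE 0.23), again the 1 gene past the threshold adjusted over the list alone. Osteocyte (median 0.97, adjusted p = 0.00288), WNT and BMP (0.43, adjusted p = 0.000212), angiogenic (0.39, adjusted p = 0.000754), stromal (0.34, adjusted p = 0.000754) and endothelial genes (0.22, adjusted p = 0.00868) were higher as sets. The immediate early and heat shock list was higher too (12 of 14 above 0, median 0.36, adjusted p = 6.73e-06), with Hspa1b, an inducible HSP70 gene, at 1.65 (SE 0.64) and Egr1 at 1.17 (SE 0.45). Every one of these lists had adjusted p = 0.51 with an estimated correlation.

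Control replicate 1 decided much of that side. Without it the osteoblast median was -0.03 (camera, adjusted p = 0.915), and the osteocyte, WNT and BMP, angiogenic, stromal and endothelial calls ended (adjusted p = 0.0907, 0.164, 0.18, 0.77 and 0.915). The osteocyte, angiogenic, stromal and endothelial calls also ended without GEL replicate 3 (0.166, 0.0508, 0.156 and 0.0934). The extracellular matrix, osteoclast and immediate early calls were kept whichever single library was left out, although their medians were 0.54 and 0.48 (matrix and osteoclast) without control replicate 1 and 0.29 and 0.12 (matrix and immediate early) without GEL replicate 3. The osteoblast median was 0.17 without GEL replicate 2 and 0.14 without GEL replicate 3, and the WNT and BMP median 0.25 without either.

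Respiratory chain genes were lower as sets in GEL than in control. Complex I had a median log2 fold change of -0.21 with 35 of 36 below 0 (camera, adjusted p = 2.17e-09), complexes II and III -0.21 (1.74e-05), complex IV -0.19 (0.00377) and complex V -0.20 (0.000194). TCA cycle (-0.18, adjusted p = 0.000396), fatty acid oxidation (-0.15, 0.000339), mitochondrial ribosome (-0.18, 9.81e-05), cytosolic ribosome (-0.11, 0.0144) and glycolysis genes (-0.32, 0.000137) were lower as well. Idh3a, a subunit of isocitrate dehydrogenase, had -0.50 (SE 0.25) and Ndufb9, a subunit of complex I, -0.31 (SE 0.16). Cell cycle genes had a median of -0.25 with 26 of 26 below 0 (adjusted p = 2.83e-06), interferon-stimulated genes -0.35 with 18 of 20 (adjusted p = 0.000604) and neutrophil genes -0.40 with 11 of 11 (adjusted p = 0.00157). Skeletal muscle genes had -1.80 with 10 of 10 below 0 (adjusted p = 0.000224), and Acta1, skeletal actin, had -2.27 (SE 1.12). With an estimated correlation the cytosolic ribosome list had adjusted p = 0.703 and each other list of this paragraph 0.51. Without control replicate 2 the muscle median was -0.02 (adjusted p = 0.199) and the TCA call ended (0.204). Leaving out control replicate 3 turned the interferon median to 0.15 (adjusted p = 0.251), and its call also ended without GEL replicate 1 (0.208). Leaving out control replicate 1 turned the cytosolic ribosome median to 0.07 (adjusted p = 0.147) and ended the complex IV, glycolysis, mitochondrial ribosome and neutrophil calls (0.776, 0.283, 0.314 and 0.742), with medians of 0.01 for glycolysis and 0.08 for neutrophils. The cytosolic ribosome median was also above 0 with quantile normalization (0.01) and with TPM (0.03), and its call ended with both (adjusted p = 0.652 and 0.313). Calls also ended without GEL replicate 2 for complex IV, complex V, the mitochondrial ribosome, the cytosolic ribosome and neutrophils (0.236, 0.0687, 0.0504, 0.719 and 0.0779), and without GEL replicate 3 for neutrophils (0.351). Without GEL replicate 1 the neutrophil median was -1.32 and the glycolysis median -0.74. Complex I and cell cycle calls were kept in every case, with medians of -0.12 for both without control replicate 1. With the neutrophil covariate 13 list calls were kept, and those of complex IV, osteocyte, WNT and BMP, cell cycle, cytosolic ribosome, angiogenic, stromal and endothelial genes ended. Kept calls with medians smaller by over 1.5 times were osteoblast (0), extracellular matrix (0.34), glycolysis (-0.11) and mitochondrial ribosome (-0.09), while the interferon median was larger (-0.57).

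Lists not past the test between GEL and control included chondrogenic genes (median 0.40, adjusted p = 0.0594), the M1 and NF-kB list (0.11, 0.0526), the M2 list (0.28, 0.104), mitochondrially encoded genes (-0.02, with a mean of 0.02, adjusted p = 0.89) and mitochondrial transport genes (-0.05, 0.186). In the M1 and NF-kB list, Ccl3 passed when adjusted over the list alone, with a log2 fold change of 1.27 (SE 0.28). No gene passed edgeR's test over all genes (0 of 15148, smallest adjusted p = 0.99). At an unadjusted p below 0.05 there were 306 genes (210 higher, 96 lower), fewer than the 757 expected by chance, and DESeq2 called 9 (3 higher, 6 lower). Groups did not overlap for 602 genes (4%, where chance gives 10%). The genes with the smallest p that met the other criteria, none past the test, were Sox18, an endothelial transcription factor (log2 fold change 0.91, SE 0.16), Mepe, Ccl3, Dcstamp and Zbtb16, a zinc finger factor (2.29, SE 0.60). On the lower side they were AY036118 (-0.82, SE 0.13), Ttr, transthyretin (-9.08, SE 1.84), Dusp1 (-1.09, SE 0.26), Ighv4-1 (-2.10, SE 0.61) and Dnajc19-ps (-0.92, SE 0.29). The last 2 are an immunoglobulin segment and a pseudogene, whose near-identical copies make their counts uncertain. Ttr, listed on chromosome 18 from 20798337 to 20807378, was at 23.2, 680 and 571 FPKM in the control, 1.15, 0.870 and 0.226 in GEL, and 7.67, 328 and 151 in Gel@MDI.

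Gel@MDI against GEL addresses what the load adds to the plain hydrogel. Neuronal, osteoblast and muscle genes were higher as sets in Gel@MDI, and neutrophil, cell cycle, ribosomal and immediate early genes lower. Exact permutation tests of the list means gave p = 0.3 for the neural, osteoblast, muscle and cytosolic ribosome lists. They gave 0.5 for neutrophil, 0.6 for cell cycle and 0.7 for immediate early and heat shock genes, so these set calls rest on camera. Neural and Schwann cell genes had a median log2 fold change of 0.87 with 8 of 8 above 0 (camera, adjusted p = 0.0014), with Map2 at 2.04 (SE 0.86) and Tubb3 at 1.73 (SE 0.74). The osteoblast list had 0.43 with 18 of 20 above 0 (adjusted p = 0.0087), with Satb2, a nuclear matrix factor of osteoblasts, at 0.99 (SE 0.57). WNT and BMP genes had 0.32 with 17 of 20 (adjusted p = 0.0253) and skeletal muscle genes 1.14 with 8 of 10 (adjusted p = 0.0432), with Myh4, a fast myosin, at 1.84 (SE 1.24). Cell cycle genes had -0.31 with 26 of 26 below 0 (adjusted p = 2.15e-05), neutrophil genes -0.95 with 11 of 11 (adjusted p = 0.000193) and cytosolic ribosome genes -0.18 with 27 of 27 (adjusted p = 0.0014). Immediate early and heat shock genes had -0.33 with 13 of 14 below 0 (adjusted p = 0.0194), with Fos at -0.98 (SE 0.37) and Fosb, a Fos family factor, at -2.59 (SE 1.06). Fosb was at 10.5 FPKM in GEL replicate 3 and between 0.0774 and 1.16 in the other libraries. All 8 lists had adjusted p = 0.957 with an estimated correlation.

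Each of these 8 calls ended when some single library was left out. Without GEL replicate 1 the osteoblast, WNT and BMP, cell cycle, cytosolic ribosome and neutrophil calls ended (camera, adjusted p = 0.552, 0.63, 0.105, 0.0512 and 0.406). Without GEL replicate 3 the immediate early median was 0.03 (adjusted p = 0.932) and the neural call ended (0.0553), and without GEL replicate 2 the muscle call ended (0.595). Leaving out Gel@MDI replicate 1 ended the WNT and BMP, cell cycle, cytosolic ribosome and muscle calls (0.0506, 0.451, 0.0506 and 0.105). Leaving out Gel@MDI replicate 2 ended the osteoblast, WNT and BMP, immediate early and muscle calls (0.3, 0.248, 0.178 and 0.343), and Gel@MDI replicate 3 the osteoblast and immediate early calls (0.115 for both). The muscle call also ended without control replicate 1 (0.0739). Without Gel@MDI replicate 1 the neural list stayed past the test (adjusted p = 0.0249) with a median of only 0.02, and without GEL replicate 2 its median was 2.02. With the neutrophil covariate the immediate early and neural calls were kept (medians -0.34 and 0.39) and those of the osteoblast, WNT and BMP, cell cycle, cytosolic ribosome and muscle lists ended. With the 3 libraries numbered 1 left out together, the neutrophil median was 0.27 and the cell cycle median 0.17, both past the camera test in that direction.

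No gene passed edgeR's test between Gel@MDI and GEL (0 of 15148, smallest adjusted p = 0.874). At an unadjusted p below 0.05 there were 456 genes (351 higher, 105 lower), again fewer than the 757 expected by chance, and DESeq2 called 5 (4 higher, 1 lower). Groups did not overlap for 1123 genes (7.4%, where chance gives 10%). The smallest p among genes that met the other criteria belonged to Ttr (log2 fold change 7.67, SE 1.75), Gabra3 (1.54, SE 0.42), Olfm1, a secreted glycoprotein of neurons (1.23, SE 0.34), Hlf, a PAR bZIP factor (1.24, SE 0.35), and Gnb5, a G protein subunit (0.79, SE 0.22). On the lower side were Pisd-ps1 (-0.47, SE 0.12), a pseudogene, and the immunoglobulin segments Ighv1-61 (-1.92, SE 0.52), Ighv1-85 (-1.61, SE 0.45), Ighv5-17 (-1.86, SE 0.53) and Igkv2-137 (-1.42, SE 0.41), all with uncertain counts because of near-identical copies. Neuronal transcripts were uneven between these libraries: cortical neuron genes had a mean log2 CPM of 6.77, 4.20 and 6.43 in Gel@MDI and 2.14, 4.85 and 2.61 in GEL. A change in genes of neurons such as Olfm1 cannot be told apart from that unevenness. Mitochondrial transport, dynamics and transfer genes had a median of 0.12 with 12 of 17 above 0 (camera, adjusted p = 0.225), where Miga1, a mitofusin partner, had 0.57 (SE 0.24). Mitochondrially encoded genes had 0.18 (adjusted p = 0.582), complex I genes -0.04 (0.544), the M1 and NF-kB list -0.02 (mean 0.05, adjusted p = 0.753) and the M2 list -0.07 (0.598).

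Both comparisons against control used the same 3 control libraries. Across the 15148 genes, which are not independent replicates, their log2 fold changes correlated with r = 0.626. A simulation that redrew all 9 libraries with no group effect, and each gene independently, gave 0.5. The covariance was 0.205 where the simulation gave 0.103, and 80.4% of genes had the same sign where it gave 66.7% (20 simulations). Since edgeR called 0 genes in each comparison, the overlap of 0 in either direction was fixed. The simulated values (0.1 higher and 0 lower) and that of independent lists (0) therefore say nothing about agreement. With 3 control libraries no split leaves 2 on each side, so part of the excess may come from the shared controls. The simulation also held no library-wide shifts such as the first principal component of these data, so the excess cannot be read as a shared effect.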

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

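Total count scaling, the covariates, the neutrophil-rich libraries left out and the libraries numbered 1 left out were chosen after the data were seen. None of the genes named for the smallest p in a comparison turned its direction in any alternative (other named genes were not compared). They were chosen for groups that do not overlap, so leaving out a library could hardly turn them. Their size did vary: between Gel@MDI and GEL the log2 fold change ranged from 0.42 to 1.52 for Hlf and from 0.5 to 1.54 for Olfm1. In each comparison edgeR's 0 genes stayed 0 apart from the settings named here. DESeq2 called 39 genes in Gel@MDI against control, 9 in GEL against control and 5 in Gel@MDI against GEL, and in simulated data it also made 58 false calls where edgeR made 1. Those data followed edgeR's own model with independent genes and no library-wide shifts, so they do not show how many of these DESeq2 calls are false. DESeq2 gave 9 genes no adjusted p. Limma with a pseudocount of 0.01 called 1 gene in Gel@MDI against control (Mir6905), and edgeR with neutrophil and neuron covariates 1 in GEL against control (Zbtb16). TPM scaling put the median of all genes at 0.263, 0.115 and 0.14 in the 3 comparisons, and other scalings at less than 0.1.

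In Gel@MDI against control, where camera called 20 lists, 13 passed with FPKM of at least 5, 11 with TPM, 11 with library weights (limma voom), 0 with an estimated correlation, 0 with directional fry and 1 with mixed fry, which was M1 and NF-kB and not among the 20. In GEL against control (22) an estimated correlation, directional and mixed fry gave 0, 0 and 0. In Gel@MDI against GEL (8) TPM gave 5, library weights 2, the 2 neutrophil-rich libraries left out 15, both covariates 5, an estimated correlation, directional and mixed fry 0, 0 and 0, and single libraries left out 5 to 10. Genes such as Ccl3 rested on few counts, 18 to 138 per library, and the part of depth was not tested.

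Lists whose direction in camera turned had the medians below, and the cause was not tested. In Gel@MDI against control, chondrogenic, angiogenic and stromal genes had -0.04, -0.05 and -0.08 with the neutrophil covariate. With both covariates the mitochondrial ribosome had 0.05, chondrogenic genes -0.38, the cytosolic ribosome 0.07 and neural genes -0.44. Interferon genes ranged from -0.63 to 0.14 with single libraries left out. In GEL against control the cytosolic ribosome had 0.03 with the neutrophil covariate and neutrophil genes 0 with both covariates, which their own mean as a covariate fixes. Ranges with single libraries left out were -0.03 to 0.69 (osteoblast), -0.71 to 0.15 (interferon), -0.22 to 0.07 (cytosolic ribosome) and -2.34 to -0.02 (muscle). Glycolysis and neutrophil medians also changed sign without control replicate 1 (0.01 and 0.08), where camera's direction stayed. In Gel@MDI against GEL, cell cycle genes had 0.02 with library weights. Without the 3 libraries numbered 1, WNT and BMP genes had -0.01, cell cycle genes 0.17 and neutrophil genes 0.27. With both covariates the cell cycle had 0.09, the cytosolic ribosome 0.09 and neural genes -0.34, and the immediate early list ranged from -0.5 to 0.03 with single libraries left out.

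The replicate numbers did not pair the libraries across all 3 groups, since 3 of 9 pairs with the same number had r above 0.1 (-0.61 to 0.73) and 3 of 9 libraries correlated best with their own number. Those 3 pairs were the ones of control with GEL (0.73, 0.42 and 0.15), and pairs with Gel@MDI lay between -0.61 and 0.04. Control replicate 2 also had 0.44 with GEL replicate 3. A pairing of control with GEL alone was not tested and stays open. With a replicate block edgeR called 0 genes in each comparison, and 20, 25 and 8 lists passed camera.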

Other observations

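Tests of brain, nerve and immediate early genes and of the osteoclast list under a covariate were chosen after the result was seen, as was the allowance for spread in reading the glucocorticoid and immediate early tests. Some transcripts typical of brain were found in all 9 libraries, at levels that differed between them: 3 of 12 cortical neuron genes and 5 of 12 brain glia genes were at 1 FPKM or more in each. The genes named here are among the most abundant of these lists. Gfap, an intermediate filament of astrocytes, ranged from 9.67 to 270 FPKM, and Slc1a2, the astrocyte glutamate transporter, from 0.949 to 56.2, both highest in Gel@MDI replicate 1. Nrgn, a postsynaptic protein of forebrain neurons, ranged from 14.6 to 146 FPKM and was highest in Gel@MDI replicate 3. The cortical neuron list had a mean log2 CPM of 6.77, 4.20 and 6.43 in Gel@MDI, 2.09, 4.84 and 2.56 in control and 2.14, 4.85 and 2.61 in GEL.

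Among clock genes, the 8 of the group with Per2 and Dbp had log2 fold changes above 0 between Gel@MDI and control, with a median of 0.87, such as Nr1d1, a heme-binding repressor (1.68, SE 0.47), and Dbp (1.08, SE 0.36). The Arntl group, which peaks at the opposite phase, had a median of 0.51, with 1 of 4 genes below 0 (Nfil3, -1.13, SE 0.38). None of these genes passed edgeR's test, and neither group was tested for enrichment. The mean log2 CPM of the Per2 and Dbp group, here with Hlf, was 3.53 in control replicate 1, 4.10 in GEL replicate 1 and 5.53 in Gel@MDI replicate 1, where the neutrophil list had 11.9, 11.74 and 9.06.

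The lists higher or lower in Gel@MDI than in control may reflect a lower share of neutrophil-lineage RNA in the Gel@MDI libraries. With the neutrophil list mean as a covariate, 36.8% of the 19 other lists (7) kept call and direction, and their median absolute log2 fold change went from 0.51 to 0.08 while the median SE of their genes went from 0.27 to 0.22, so the folds shrank on the median and the errors did not grow. The interferon list went the other way, from a median of -0.32 to -0.71 (camera, adjusted p = 2.67e-09), so the covariate did not shrink every list. Its call rested on control replicate 3, without which the median was 0.14 (camera with no covariate, adjusted p = 0.832). The neutrophil mean moves with the group (exact permutation p = 0.1, the smallest possible), so this share of RNA and an effect of the treatment on cell content cannot be told apart. Without control replicate 1, 75% of the lists were kept, which leaves its part open, and the osteoclast list was kept with the covariate (median 0.88 without it and 0.7 with it), and the difference in its mean was 0.64 (SE 0.33) with it and 0.77 (SE 0.25) without, between the bounds set for either reading.

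The neuronal transcripts may come from brain tissue carried over with the bone, since the cortical neuron and brain glia lists correlated with r = 0.82 over the 9 libraries (permutation p = 0.00423, adjusted over 3 relations 0.0127), and 0.71 without Gel@MDI replicates 1 and 3. Of the glia list 1 gene is in a fixed list, and no sort is given in the labels that would remove such cells. Peripheral nerve gave r = 0.72 (permutation p = 0.0268, adjusted 0.0402) and 0.52 without those 2 libraries, and stays open. In the third relation the cortical neuron and choroid plexus lists gave r = 0.32 (permutation p = 0.389, adjusted 0.389), so a shared source of the 2 was not shown. Ttr has a candidate source in choroid plexus, whose 7 other genes correlated with it with a median r of 0.75 (Folr1 0.92, Enpp2 0.85), short of the bound of 0.8. Clic6 and Sostdc1 were left out of these 7. No biological explanation was tested for this pattern.

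Lower Per1 and Dusp1 in Gel@MDI than in control might reflect the time of day, glucocorticoids or handling at collection, and no test decided once spread was allowed for. The Per2 and Dbp group differed from the Arntl group by 0.37, between the bounds set for either reading, and Hlf, seen before, was left out (with it 0.37). These bounds took no account of direction. All 8 genes of the Per2 and Dbp group were above 0 (median 0.87, from 0.39 to 1.68), opposite to Per1 (-1.13). Those 8 genes argue against a time of day at which their group is lower, and other times stay open. Other glucocorticoid-induced genes had a median of 0.1, past the bound set beforehand against a lower glucocorticoid response. An allowance for their standard error, added after the values were seen, left this reading open, since 5 of 10 were below 0 and the SD was 0.71. Fkbp5 and Zbtb16, seen before, were left out (with them 0.22). Other immediate early genes had a median of -0.21 with 7 of 11 below 0 and an SD of 0.8. An effect of the treatment stays open as well, untested.

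Splits of 3 against 3 libraries number 10, too few for a share under 0.05. In Gel@MDI against control the counts were 0 genes past edgeR's test (highest other split 0, and 10 splits gave as many), 1834 at an unadjusted p below 0.05 (highest other 1039, 1 split as many), 39 by DESeq2 (highest other 94, 2 splits) and 20 lists (highest other 26, 4 splits). In GEL against control they were 0 (highest other 5, 10 splits), 306 (5372, 7 splits), 9 (3801, 5 splits) and 22 lists (24, 2 splits). In Gel@MDI against GEL they were 0 (0, 10 splits), 456 (1318, 5 splits), 5 (301, 3 splits) and 8 lists (22, 10 splits). The split that put control replicates 1 and 3 with GEL replicate 1 gave 5372 genes at an unadjusted p below 0.05 and 3801 by DESeq2, which points to a structure of the samples other than the treatment.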
